A study of Homo sapiens with 6 samples.

How the data were processed

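The files analysed here are raw droplet matrices of 2 single-cell RNA-seq libraries and 2 tables of transcription factor (TF) barcode counts, each table paired with 1 of the libraries. The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and droplet, with no cell selection and no normalization. They were made with Cell Ranger 3.0.2 on the genome build GRCh38, per the submitters' processing notes. Per the labels' protocols, the libraries came from a droplet kit that reads the 3 prime ends of transcripts, so a count tells how many captured RNA molecules ended in a gene and says little about which isoform was present. The labels name 2 versions of this kit and do not say which library used which. The deposited TF tables hold counts per cell and TF, made by PCR from the cDNA per the labels. Whether these are counts of reads or of UMIs is not given in the sources used here, and PCR reads without molecular identifiers are not independent molecules. The labels list 2 sequencing runs for each library, and each library had 1 matrix, so both runs were treated as 1 sample.

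Droplets were counted as cells when their UMI total reached 1/10 of the 99th percentile of the 5000 largest barcodes of the library, which was 7967 UMIs in library 1 and 7850 in library 2. Cells with under 1000 genes or over 20% mitochondrial UMIs were left out. Scrublet's own threshold marked 13 and 10 cells as doublets, 0.252% and 0.194% of cells, which is too few for libraries of this size. The 4% of cells with the highest doublet score were therefore removed, as had been fixed for that case. Cells tied with the last score were removed too, which made 220 cells in library 1 and 212 in library 2. The cells kept numbered 4929 and 4946. Of 33694 genes in the matrices, 32807 had a current symbol in the gene name table, and 34 symbols were shared by more than 1 gene. Symbols are printed as the files give them, for example LECT1, SQRDL and FYB, which have newer names. Genes with near-identical copies, such as the HLA genes, SERPINB and S100A families, depend on how the aligner placed shared reads.

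A TF was called in a cell when its barcode count was 3 or more and made up 5% or more of the cell's TF counts. The alternative call at 1 count dropped the rule on the share. Cells with at least 1 called TF are named barcoded and cells with none unbarcoded. The unbarcoded cells include 108 cells in library 1 and 90 in library 2 that have no line in the TF table, which were counted as having no TF. Because a cell can carry several TFs, the cells of 1 TF differ from the rest in that TF and in whichever others it happened to carry.

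UMI counts were summed over the cells of each group within each library. The sums were compared with edgeR 4.0.16, using TMM scaling, filterByExpr, the quasi-likelihood test with library as a block, and Benjamini-Hochberg adjustment over genes, at an adjusted p under 0.05. Each fit had 4 sums, 2 per group, and a TF entered with 20 or more cells per library in each group. The labels give both amplicon and both RNA libraries the numbers 1 and 2, and both cell groups of a comparison lie in each library, which is why library is a block. Fold changes are log2 values from the fit, given with the fold of each library alone or with CPM, the UMIs of a gene scaled to a fixed total per sum, as mean ± SD over 2 libraries. Folds of single libraries were taken with a small added count, and for genes with few UMIs they can lie well to either side of the fold of the fit. The 2 libraries may be repeat preparations of the same culture, so their spread may leave out differences between cultures. Standard errors of the fits lie close to counting error, because the spread of single genes was pulled towards a trend over all genes, and adjusted p-values are correspondingly small. An adjusted p printed as a list call comes from camera in limma 3.58.1 with a preset correlation between genes of 0.01. Each such call was repeated with the correlation estimated from the sums. That version rests on the residual degrees of freedom of 4 sums, which leave a list almost no prospect of passing. In barcoded cells the microglia list had an estimated correlation of 0, under the preset, yet its unadjusted camera p went from 0.0015 to 0.18. A list that did not pass there is therefore neither upheld nor overturned by it. DESeq2 1.42.0 was run as an alternative. Other software was R 4.3.3, Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

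The tests were tested on simulated data drawn from the real means and library sizes, with seeded genes changed by known folds. For barcoded against unbarcoded cells, 64% of genes changed 1.5-fold and 70.8% of genes changed 2-fold were recovered. For SPI1 these shares were 67% and 83.7%, for HCLS1 38.8% and 56.1%, and for FLI1 10.9% and 23.2%. The false share of all calls was 7.69% for barcoded cells, 5.10% for SPI1, 7.92% for HCLS1 and 2.94% for FLI1. The simulation drew each gene independently with the spread of the fit and left out differences in other carried TFs. It gave 8, 8 and 1 false calls for SPI1, HCLS1 and FLI1. Random sets of barcoded cells of these sizes gave medians of 30.5, 27 and 60 calls, so the real sums can hold more false calls than these shares say. For the test of whether the effect of CEBPA differs with SPI1, 57.6% of genes changed 2-fold were recovered and 14.3% of calls were false. No random sets of cells were run for that test.

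Apart from the tests, the alternative and the genes that the text describes as chosen after the data were seen, the comparisons, thresholds, alternatives, 14 gene lists and the rule for named genes were fixed before the data were examined. The rule for barcoded cells took the 10 called genes with the largest positive and the 10 with the largest negative fold change, with mean log2 CPM over 5 and the same direction in each library. For the 5 TFs with the most called genes and for SPI1, CEBPA and FLI1 it took 4 up and 2 down with mean log2 CPM over 3, and for SPI1 combinations 4 up and 2 down. It left out the TF genes of the pool, clone names, mitochondrial and ribosomal protein genes and sex-linked markers. From each list it took up to 4 called members with the largest fold change, and up to 8 for the microglia and myeloid lists of a TF whose list passed. Every pick by largest fold is printed. Some items are not reported here. Of the picks by list, examples are printed, and these were selected after their values had been seen. Genes outside the rule are AIF1, CD53, PTPRC and CD33 in the comparison of SPI1 cells with and without CEBPA, and HLA-DRA, HLA-DRB1 and CD74 in CIITA cells. They were chosen after their values were seen.

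The lists cover microglia, leukocyte and myeloid, pluripotency, endothelial, erythroid and megakaryocyte, neural, primitive streak and mesoderm, endoderm, trophoblast and simple epithelium, mesenchymal, cell cycle, stress and p53, inflammatory, and interferon and MHC class I genes. TFs of the pool were taken out of each list. Cells were thinned to 16053 UMIs each as an alternative, which left out 462 and 449 barcoded and 43 and 34 unbarcoded cells of the libraries as too shallow. Clusters were found with the Leiden method at a resolution of 0.5 on both libraries together.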

Results

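The study screened 40 transcription factors (TFs) at once for their ability to turn on microglia genes in human stem cells, as its title states. Microglia are the resident macrophages of the brain. The cells were PGP1, an established human induced pluripotent stem cell line. TF vectors were inserted into the genome with the PiggyBac transposase, and each vector carried a barcode naming its TF. Doxycycline switched the TFs on for 4 days, and cells that no longer stained for Tra-1-60, a surface antigen of pluripotent cells, were sorted for sequencing. Undifferentiated stem cells were added at 10% as a control. Because the sort selected against this antigen, low pluripotency genes in the sorted cells are in part expected.

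RNA and TF barcodes were both read from each of 2 single-cell libraries, giving 2 RNA profiles and 2 barcode tables. Library 1 held 178370246 UMIs and library 2 held 176276290. After filtering, 4929 and 4946 cells remained, with medians of 28860 and 28800 UMIs and 5799 and 5812 genes per cell. The median mitochondrial share was 10.4% in library 1 and 10.8% in library 2. The barcode tables held 2020302 and 1978160 counts over 5319 and 5381 cells.

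Which TFs the cells carried was read from the barcodes. At least 1 TF was called in 91.7% of cells in library 1 (4520 cells, 95% exact interval 90.9% to 92.5%) and in 93.6% in library 2 (4627 cells, 92.8% to 94.2%). Cells carried 4.14 ± 2.00 TFs in library 1 and 4.33 ± 1.96 in library 2 (SD over cells), and 4.30% and 3.80% of cells carried exactly 1. CEBPB was the most frequent TF, in 43.0% and 45.0% of cells, followed by CEBPA, in 39.7% and 39.9%. SPI1, the gene of the macrophage regulator PU.1, was called in 575 cells (11.7%) and 739 cells (14.9%). FLI1 was rare, with 27 and 34 cells. NFATC2 and CTCF were called in 0 cells of either library, which allows a share of up to 0.0748% and 0.0746%. With them HIF1A, IFI16, SALL1, MNDA, RREB1 and MEF2C had too few cells for a test. These intervals cover counting error only. A TF call that needed only 1 count and no share of the cell's TF counts, named the TF call at 1 count below, raised the mean share of cells with a TF from 92.6% to 98.0%, and the number of TFs per cell to 14.3 and 15.6.

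**Figure D1:**
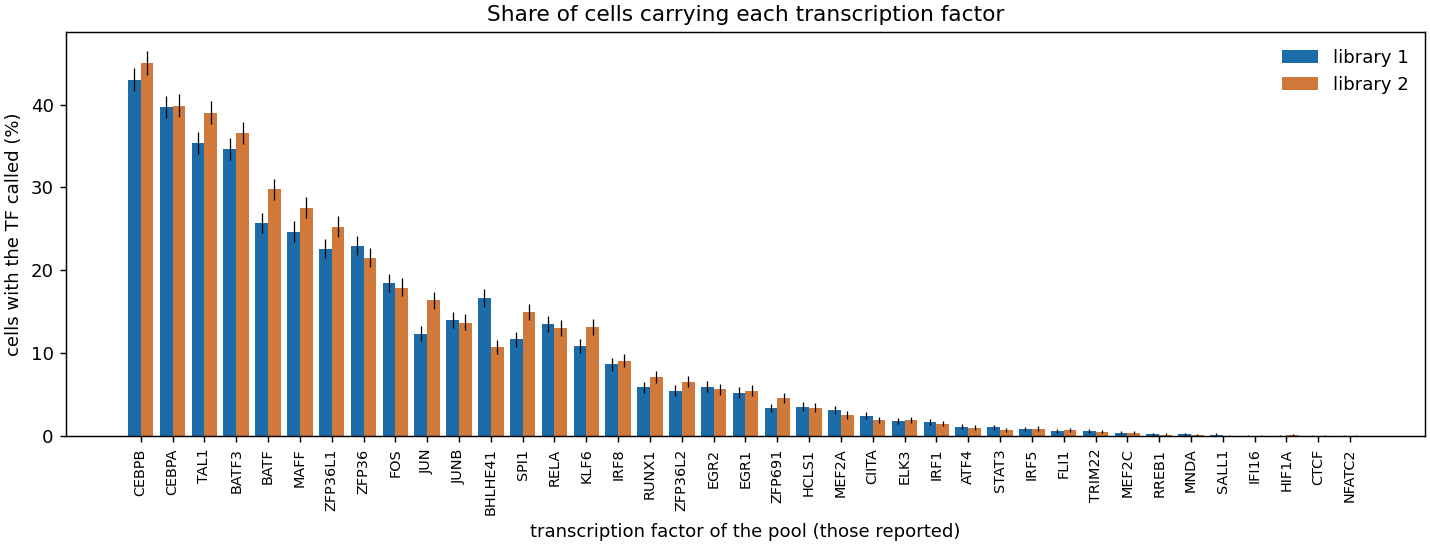
Share of cells with each reported TF of the pool called, in percent of the kept cells, for library 1 and library 2. Bars give the share and lines its 95% exact binomial interval, and CEBPB and CEBPA lie highest at 39.7% to 45.0% in both libraries.

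Cells with a TF were compared with cells without a called TF to learn how cells of the pool differed from stem cells. Leukocyte and myeloid genes were far higher in barcoded cells and pluripotency genes far lower. S100A9, a calcium-binding protein of neutrophils and monocytes, stood at 1453 ± 107 CPM against 35.7 ± 26.5 (mean ± SD, n = 2 libraries), a log2 fold change of 5.44 (6.49 and 4.66 in the libraries). POU5F1 (ENSG00000204531), which encodes the pluripotency factor OCT4, fell from 1396 ± 4.21 to 171 ± 24.7 CPM, by 3.03 log2 units. Of 18660 genes tested with edgeR's quasi-likelihood test, 6594 rose and 6085 fell, and 2917 and 1747 of these did so at least 2-fold. The total of 12679 called genes became 8359 with DESeq2 and 8433 with the TF call at 1 count. The cells without a called TF were deeper, with medians of 45206 and 43983 UMIs against 28058 and 28165.

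Among genes with a mean log2 CPM over 5, strong rises were seen in the plasma protein HP (haptoglobin, log2 fold change 6.13, 6.79 and 5.52 in the libraries), the protease inhibitors SLPI (5.93, 6.02 and 5.80) and PI3 (5.16, 6.00 and 4.40), and the retinol carrier RBP4 (5.50, 5.84 and 5.15). The arginine-degrading enzyme ARG1 rose by 5.67 (6.11 and 5.13), the carboxylesterase CES1 by 5.72 (5.68 and 5.69), and SQRDL, a mitochondrial sulfide oxidase, by 5.66 (5.45 and 5.90). The fatty acid elongase ELOVL3 rose by 5.55 (5.42 and 5.69) and the phospholipid-binding protein ANXA1 by 5.20 (5.22 and 5.16). Strong falls above the same level, besides POU5F1, were in MT1G, a metallothionein (−4.27, −4.47 and −4.01), FOXD3-AS1 (−4.18, −4.05 and −4.33), the NODAL co-receptor TDGF1 (−3.76, −3.63 and −3.89) and FOXH1, a NODAL pathway factor (−3.44, −3.38 and −3.50). LECT1 fell by 3.15, SCG3 by 3.01, the telomere protein TERF1 by 2.96, the de novo DNA methyltransferase DNMT3B by 2.89 and the RNA polymerase III subunit POLR3G by 2.88. FOXD3-AS1 is antisense to FOXD3, and whether the counts used strand is not given in the sources used here.

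Of 14 gene lists fixed beforehand, 8 were called in this comparison by camera with a preset correlation. In the leukocyte and myeloid list 19 of 21 tested members rose and 0 fell (19 adjusted over the list alone), with a median log2 fold change of 3.61 (adjusted p = 4.5e-05 with the preset and adjusted p = 0.436 with an estimated correlation). LAPTM5, a lysosomal protein of blood cells, rose by 6.98 (7.54 and 6.19), the granule proteoglycan SRGN by 6.17 (5.05 and 6.41) and the protease CTSS by 5.32 (4.27 and 6.71). In the microglia list 13 of 16 rose and 2 fell (15 adjusted over the list alone, 13 of them up), with a median of 2.12, or 1.95 with undetected genes at their bound (adjusted p = 0.0034 with the preset and adjusted p = 0.436 with an estimated correlation). CSF1R, the receptor for the macrophage growth factor CSF1, had 456 UMIs in barcoded cells and 0 in unbarcoded cells, and was at least 16.3-fold higher, taking 3 counts over the group as the floor. The complement genes C1QC and C1QB were at least 5.93-fold and 3.90-fold higher, and the microglial receptor TREM2 rose by 6.04 (5.45 and 6.13). All 13 pluripotency genes fell (13 adjusted over the list alone, median −2.81, adjusted p = 4.9e-07 with the preset and adjusted p = 0.436 with an estimated correlation), among them UTF1 (−3.68, −3.46 and −3.89) and NANOG (−3.28, −3.22 and −3.33).

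Further lists that rose were the mesenchymal, with 13 of 16 members up and 1 down (14 adjusted over the list alone), the inflammatory, with 9 of 11 up and 1 down (10), and the interferon and MHC class I list, with 11 of 12 up and 1 down (12). These lists, and the neural and cell cycle lists below, had an adjusted p of 0.436 with an estimated correlation. The collagen-binding LUM rose by 4.29 (5.59 and 3.46), smooth muscle actin ACTA2 by 4.10 (4.02 and 4.16), vimentin VIM by 2.74 (2.57 and 2.95) and COL1A1, a chain of type I collagen, by 2.64 (2.53 and 2.79). The chemokines CCL4 and CCL3 rose by 7.11 (7.39 and 5.75) and 5.50 (7.11 and 3.83) and the cytokine IL1B by 4.57 (5.06 and 3.03), each from 1 or 2 UMIs in unbarcoded cells. OAS1, HLA-B and B2M rose by 2.67 (2.76 and 2.44), 2.00 (1.98 and 2.02) and 1.99 (1.93 and 2.07). The neural list fell, with 9 of 13 members down (9 adjusted over the list alone) and the neurofilament genes NEFM and INA at −2.46 (−2.54 and −2.37) and −2.36 (−2.26 and −2.45). In the cell cycle list 12 of 15 members fell and 3 rose (15 adjusted over the list alone), with UBE2C at −1.01 (−0.97 and −1.05), CDK1 at −0.75 (−0.68 and −0.84) and TYMS at 0.68 in both libraries.

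The remaining lists were not called in barcoded cells. The endothelial median was −0.13 over both libraries but 0.23 and 0.24 in the single libraries, so its sign is not settled. Medians were −0.20 for erythroid and megakaryocyte (−0.44 and −0.38 in the libraries) and 1.32 for primitive streak and mesoderm (1.04 and 1.15). They were 0.64 for trophoblast and simple epithelium (0.73 and 0.60) and 0.53 for stress and p53 (0.66 and 0.37). The median of the endoderm list was 1.33, or 0.44 with undetected genes at their bound. No list call held when the correlation between genes was estimated (adjusted p = 0.436 with an estimated correlation for each of the 8 called lists). With the TF call at 1 count the interferon list lost its call, and the rise of C1QB no longer passed under that call or DESeq2.

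Each TF was then compared with all other barcoded cells, to ask what it added to a background of other TFs. In 32 TFs with enough cells, the TF's own gene could be tested for 31, and it rose in 31, by at least 0.40 log2 units with a median of 3.07. SPI1 rose by 4.30 in SPI1 cells, CEBPA from 4.85 to 110 CPM in CEBPA cells, and FLI1 by 3.71 in FLI1 cells (2.92 and 4.28 in the libraries). ZFP691 could not be tested. All 32 TFs had 10 or more changed genes. That count needs a comparison, since 20 random sets of barcoded cells the size of the SPI1 group gave 5 to 77 calls (median 30.5), sets the size of HCLS1 gave 1 to 140 (median 27) and sets the size of FLI1 gave 0 to 193 (median 60). The number of called genes was above 140 for 30 TFs, while ZFP691 (121) and HCLS1 (50) lay within the range of random sets. In the main fit CEBPA had the most changed genes (11317), followed by CEBPB (7746), ZFP36 (7654), ZFP36L1 (5862) and JUN (5148). The TFs differ in cell number, and the order was not the same with DESeq2, which called 3299 genes for ZFP36 and 2858 for CEBPB. The fits also differed in how strongly the spread of single genes was pulled towards the trend. That pull was complete for ELK3, where 86 and 94 cells gave 2530 calls. It was weak for HCLS1, where 173 and 169 cells gave 50. The numbers of called genes and their order are thus not strictly comparable between TFs. Among cells that carried exactly 1 TF, only CEBPB and TAL1 had enough cells for a test, and both had 10 or more changed genes.

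The microglia or the myeloid list was raised for 10 of the 32 TFs. Among them, the microglia list rose with SPI1, KLF6 and TAL1, and the myeloid list with SPI1, KLF6, CEBPA, FLI1, IRF1, FOS, BATF3 and HCLS1. The myeloid list was lowered for 7 TFs and the microglia list for 3. Pluripotency genes were the list with most calls, lowered for 23 TFs and raised for 5 in relation to other barcoded cells. Some barcoded cells lay in the pluripotent-like clusters described below. Their share in each TF group was not measured, so these calls may reflect that share rather than an effect of each TF. Across the 448 pairs of list and TF, 42 were raised and 65 lowered by camera with a preset correlation, and none passed with an estimated one (lowest adjusted p = 0.895 with an estimated correlation). With unbarcoded cells as the reference in place of other barcoded cells, all 32 TFs had a raised microglia or myeloid list, and with the TF call at 1 count the number was 35 of 40 TFs tested. Neither count speaks for single TFs. Barcoded cells as a whole already had a raised myeloid list against unbarcoded cells. With the TF call at 1 count, unbarcoded cells fell from 409 and 319 to 108 and 90, so most of them entered as barcoded cells.

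**Figure D2:**
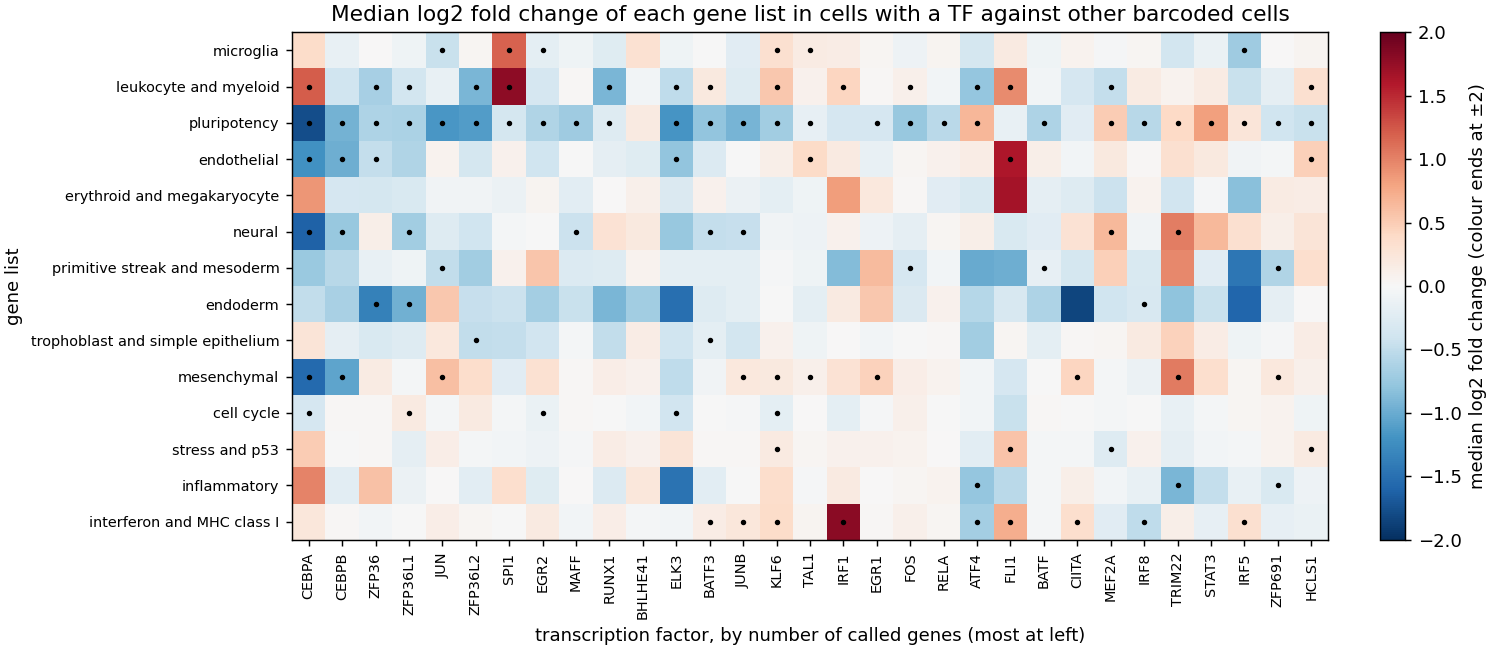
Median log2 fold change of each fixed gene list (rows) in cells with each reported TF (columns) against other barcoded cells, with colours ending at 2 log2 units either way. Dots mark lists called by camera with the preset correlation, and SPI1 and KLF6 have dots for both the microglia and the myeloid list.

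CEBPA, a factor of granulocyte, monocyte, liver and fat cell differentiation, was called in 1958 and 1973 cells. Leukocyte and myeloid genes were higher in CEBPA cells than in other barcoded cells, and pluripotency and mesenchymal genes were lower. Arginase ARG1 stood at 127 ± 16.3 CPM against 1.99 ± 0.69 (n = 2 libraries), a log2 fold change of 5.99 (6.50 and 5.53). The channel AQP9 rose by 5.81 (6.12 and 5.43), the neutrophil protein S100A12 by 5.78 (5.92 and 5.60) and the adaptor FYB by 5.54 (6.03 and 5.07). FOXH1 and TDGF1 fell by 3.58 (4.06 and 3.15) and 3.12 (3.48 and 2.79). In total 5761 genes rose and 5556 fell of 18484 tested.

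In CEBPA cells 14 of 21 leukocyte and myeloid genes rose and 3 fell (17 adjusted over the list alone, 14 of them up), with a median of 1.21. CYBB, the catalytic part of the phagocyte oxidase, rose by 4.89 (5.23 and 4.28), lysozyme LYZ by 4.88 (5.37 and 4.40), S100A8 by 4.45 (4.84 and 4.07), SRGN by 4.10 (3.34 and 5.32) and S100A9 by 3.30 (3.46 and 3.13). The cytokine receptors CSF2RA and CSF3R rose by 3.03 (3.24 and 2.74) and 2.56 (2.63 and 2.47), and CTSS by 2.60 (2.88 and 2.28). For the myeloid list camera gave an adjusted p = 0.0052 with the preset and 0.895 as adjusted p with an estimated correlation, as it did for the CEBPA lists named next. The microglia list was not called (9 of 16 up, 3 down, 12 adjusted over the list alone, median 0.36), although GPR34, TREM2 and the complement gene C3 rose by 3.41 (3.75 and 2.94), 2.49 (2.88 and 2.15) and 2.46 (2.57 and 2.34). All 13 pluripotency genes fell (13 adjusted over the list alone, median −1.77), with UTF1 at −3.67 (−4.06 and −3.21), LIN28A at −2.97 (−3.18 and −2.76) and NANOG at −2.60 (−2.60 and −2.55). Of 12 neural genes 11 fell (11 adjusted over the list alone), NES by 3.01 (2.99 and 3.01). Of 16 mesenchymal genes 12 fell and 2 rose (14 adjusted over the list alone), with THY1 at −3.00 (−3.13 and −2.87) and COL1A2 at −2.89 (−2.81 and −2.98). The endothelial (11 of 16 down, 2 up, 13 adjusted over the list alone) and cell cycle lists (13 of 15 down, 1 up, 14 adjusted over the list alone) were also lowered. CEBPA is among the TFs carried forward by the study from these libraries, so its lists are not independent evidence. DESeq2 called 6416 genes.

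CEBPB, a close relative of CEBPA, was carried by 2119 and 2227 cells. In these cells DLK1, a membrane protein of fat cell precursors, rose by 4.10 log2 units (4.33 and 3.86) to 76.9 ± 11.7 CPM, and the myeloid fatty acid receptor GPR84 rose by 2.50 (2.37 and 2.63). The WNT antagonist FRZB rose by 2.05 (2.00 and 2.10) and the fucosyltransferase FUT3 by 1.93 (2.01 and 1.83). Both FYB and LYZ were lower than in other barcoded cells, by 4.41 (3.86 and 5.37) and 3.00 (2.80 and 3.27). This order depended on the reference, because against unbarcoded cells FYB and LYZ were higher by 2.43 and 2.81, and with CEBPA and SPI1 cells left out, a comparison chosen after seeing the data, LYZ was higher by 0.29. With the TF call at 1 count FYB, LYZ and COL1A2 were higher too. CEBPA itself was carried by 49.2% and 45.1% of CEBPB cells and by 38.1% and 40.4% of other barcoded cells. The lists lowered with CEBPB were pluripotency (13 of 13 down, 13 adjusted over the list alone), mesenchymal (14 of 16 down, 1 up, 15 adjusted over the list alone), endothelial (11 of 16 down, 1 up, 13 adjusted over the list alone) and neural (9 of 12 down, 10 adjusted over the list alone). COL1A2 was at −2.22 (−2.32 and −2.12) and TAGLN at −1.42 (−1.57 and −1.27), and against unbarcoded cells TAGLN no longer passed the test. Neither the microglia list (2 of 17 up, 8 down, 10 adjusted over the list alone) nor the myeloid list (4 of 21 up, 12 down, 16 adjusted over the list alone) was called. For the 4 called lists the adjusted p was 0.895 with an estimated correlation. Altogether 3764 genes rose and 3982 fell, and DESeq2 called 2858.

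ZFP36 and ZFP36L1 encode proteins that bind AU-rich elements in messenger RNA and speed its decay. Cells with ZFP36 had less RNA of leukocyte and myeloid genes than other barcoded cells. The tachykinin gene TAC1 fell by 2.88 (3.25 and 2.48), the protease inhibitor SERPINB2 by 2.79 (2.65 and 2.99), and 14 of 21 myeloid genes fell with 0 rising (14 adjusted over the list alone, median −0.66). Among these were SRGN at −3.33 (−2.80 and −4.09), LYZ at −2.74 (−4.05 and −1.83), FCER1G at −1.93 (−1.88 and −1.95) and S100A8 at −1.66 (−1.80 and −1.51). The increases were smaller, with the cytokine IL32 at 1.28 (1.37 and 1.19), EFEMP1 at 1.22 (1.10 and 1.32), the kinase PRKG1 at 1.18 (1.04 and 1.30) and the chemokine CCL5 at 1.17 (1.36 and 0.98). Against unbarcoded cells, TAC1, SERPINB2, LYZ, FCER1G and S100A8 were higher in ZFP36 cells by 1.02, 2.83, 2.47, 1.69 and 3.22, so that these falls hold in relation to other TF cells. With the TF call at 1 count TAC1, SRGN and FCER1G were higher and LYZ and S100A8 no longer passed, and SERPINB2 lost its call without CEBPA and SPI1 cells. Pluripotency (11 of 13 down, 2 up, 13 adjusted over the list alone), endothelial (6 of 16 down, 6 adjusted over the list alone) and endoderm genes (7 of 9 down, 8 adjusted over the list alone) also fell in ZFP36 cells. For the 4 called lists the adjusted p was 0.895 to 0.899 with an estimated correlation. ZFP36 cells were shallower, with medians of 24567 and 25314 UMIs against 29443 and 29217.

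In ZFP36L1 cells myeloid and pluripotency genes were lower than in other barcoded cells. CCK, a gut and brain peptide, fell by 2.49 (2.05 and 3.14), IGFBP5 by 1.88 (1.92 and 1.81), FCER1G by 1.69 (1.75 and 1.60) and S100A8 by 1.48 (1.38 and 1.59). The interferon-induced chemokine CXCL10 rose by 1.31 (0.59 and 1.84), CCL5 by 1.03 (0.93 and 1.13), LEFTY2, a NODAL antagonist, by 0.88 (0.83 and 0.93) and NPW by 0.82 (0.99 and 0.66). In the myeloid list 9 of 21 members fell and 0 rose (11 adjusted over the list alone, median −0.36), and all 13 pluripotency genes fell (13 adjusted over the list alone, median −0.64), with an adjusted p of 0.895 for both with an estimated correlation. Against unbarcoded cells CCK, FCER1G and S100A8 were higher, by 0.23, 1.94 and 3.45, and with the TF call at 1 count FCER1G and S100A8 were higher and LEFTY2 lower. CXCL10 no longer passed under DESeq2, which called 1969 genes against 5862.

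JUN, a subunit of the AP-1 factor, was carried by 609 and 809 cells. Mesenchymal genes were higher in them. The caveolae protein CAV1 rose by 2.83 (2.80 and 2.84) to 55.0 ± 1.47 CPM, the carbonic anhydrase CA3 by 2.41 (2.43 and 2.38), S100A16 by 2.33 (2.37 and 2.29) and the cytokine IL11 by 2.16 (2.18 and 2.13). FOXH1 and TDGF1 fell by 2.73 (2.34 and 3.12) and 2.27 (2.35 and 2.20). Of 16 mesenchymal genes 10 rose and 1 fell (13 adjusted over the list alone, 11 of them up), including the smooth muscle gene CNN1 at 2.11 (2.15 and 2.07), COL1A1 at 1.69 (1.65 and 1.73) and COL1A2 at 1.33 (1.39 and 1.27). All 13 pluripotency genes fell (13 adjusted over the list alone), the microglia list was lowered (7 of 15 down, 3 up, 11 adjusted over the list alone), and so was the primitive streak list (4 of 10 down, 4 adjusted over the list alone). For these lists the adjusted p was 0.895 with an estimated correlation. DESeq2 called 1493 genes and the test without the library block 3658, against 5148.

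SPI1 had the largest median rise of both the microglia and the myeloid list among the 32 TFs. AIF1 (ENSG00000204472), which encodes IBA1, the usual stain for microglia, stood at 92.9 ± 8.44 CPM in SPI1 cells and 7.46 ± 0.34 in other barcoded cells (n = 2 libraries), a log2 fold change of 3.64 (3.68 and 3.59, edgeR quasi-likelihood adjusted p = 5.2e-27 by Benjamini-Hochberg). LST1, a leukocyte gene of the MHC region, rose by 3.40 (3.42 and 3.37), LAPTM5 by 3.33 (3.19 and 3.45) and LYZ by 2.90 (2.85 and 2.96). CCK and FOXD3-AS1 fell by 1.97 (1.36 and 2.96) and 1.93 (1.72 and 2.16). Altogether 2665 genes rose and 2036 fell of 18379. A UMI of AIF1 was found in 74.9% and 76.4% of SPI1 cells without CEBPA, in 18.3% and 17.9% of barcoded cells with neither TF, in 6.33% and 5.62% of CEBPA cells without SPI1 and in 34.2% and 38.2% of the deeper unbarcoded cells. With cells thinned to equal depth these shares were 62.8% and 66.0%, 11.7% and 11.9%, 3.44% and 3.09%, and 14.2% and 16.5%. The share of such UMIs that came from other cells through the droplet fluid was not measured.

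In SPI1 cells 13 of 18 microglia genes rose and 1 fell (17 adjusted over the list alone, 15 of them up), with a median of 1.18 (1.15 and 1.01). The complement genes C1QB, C1QA and C1QC rose by 4.75 (3.60 and 5.08), 3.80 (2.69 and 3.74) and 3.74 (3.35 and 3.84), the purine receptor P2RY13 by 4.41 (4.55 and 3.43) and CSF1R by 2.12 (1.89 and 2.29). The fructose transporter SLC2A5 and the microglial surface protein TMEM119 rose by 1.93 (0.85 and 2.78) and 1.23 (1.18 and 1.24). Levels were low, with 29 UMIs of C1QA and 90 of C1QB over all SPI1 cells. Of 21 leukocyte and myeloid genes 16 rose and 2 fell (19 adjusted over the list alone, 17 of them up), with a median of 1.79 (1.80 and 1.42). The receptor adaptor TYROBP rose by 4.56 (4.90 and 4.10), CD53 by 4.49 (4.12 and 4.74), PTPRC, the pan-leukocyte antigen CD45, by 3.89 (3.50 and 3.97), CD33 by 3.01 (2.60 and 3.30), the integrin ITGB2 by 2.47 (2.50 and 2.42) and the actin regulator CORO1A by 2.39 (2.43 and 2.35). A UMI of PTPRC was found in 3.94% and 4.81% of SPI1 cells without CEBPA, against 0.544% and 0.364% of barcoded cells with neither TF, at medians of 30265 and 27741 against 29435 and 29262 UMIs. Of 13 pluripotency genes 11 fell (12 adjusted over the list alone), with a median of −0.34 and UTF1 and L1TD1 at −1.06 (−0.67 and −1.50) and −0.51 (−0.37 and −0.65).

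The adjusted p of these lists in SPI1 cells was 2.0e-05 for microglia, 5.4e-09 for myeloid and 0.0023 for pluripotency genes by camera, and 0.895, 0.895 and 0.897 as adjusted p with an estimated correlation. No other list was called in SPI1 cells, although single members rose, such as the endoderm genes CER1 by 3.84 (3.09 and 4.40) and FOXA2 by 3.50 (3.84 and 2.89) and the primitive streak gene MIXL1 by 1.81 (1.83 and 1.77). The endoderm list had a median of −0.43 and a mean of 0.30. Since SPI1 is a TF the study took forward from these libraries, the lists are not independent evidence. CCK lost its call without CEBPA cells and was higher by 0.58 against unbarcoded cells and by 0.33 with the TF call at 1 count, SLC2A5, UTF1 and L1TD1 lost theirs with the stricter TF call, SLC2A5 also without the library block and with doublets kept, and TMEM119 with the stricter cell filter and under DESeq2, which called 1527 genes, 70.7% of them up against 56.7%.

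**Figure D3:**
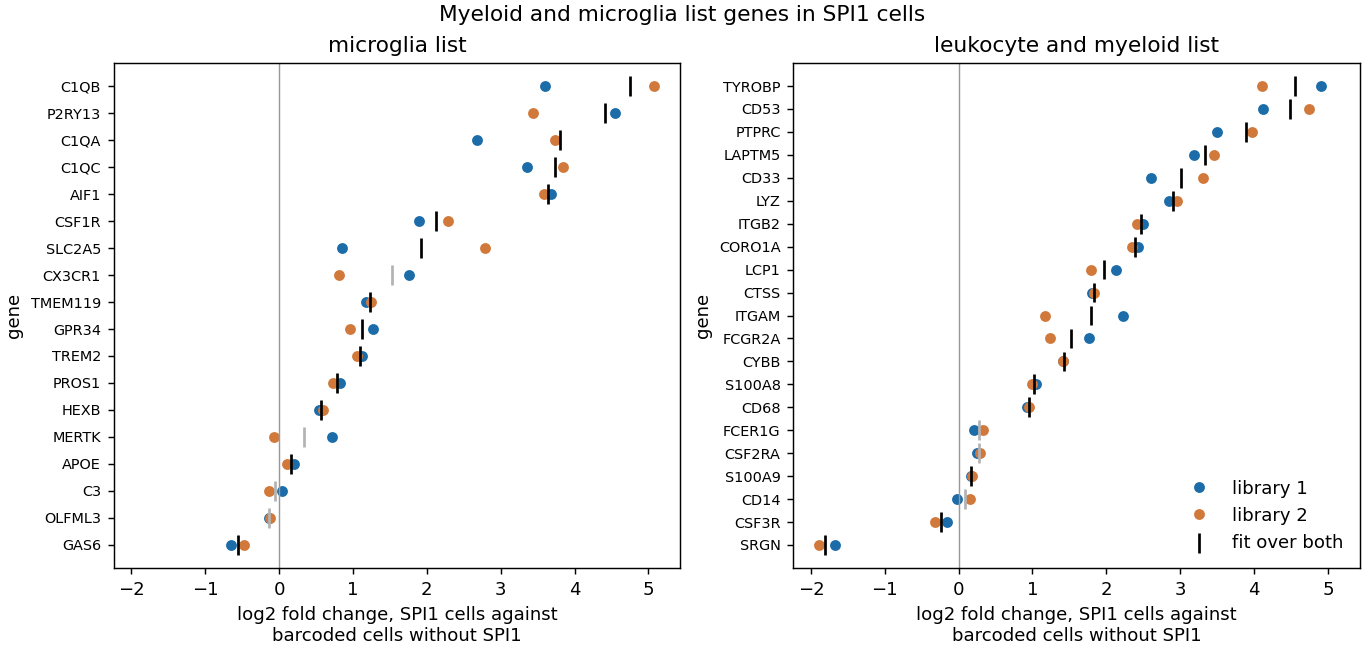
Log2 fold change of microglia, leukocyte and myeloid genes in SPI1 cells against other barcoded cells. Coloured points give each of the 2 libraries and vertical ticks the fit over both, black where the gene was called and grey where not, and most of the 39 genes lie to the right of 0.

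FLI1, an ETS factor of blood vessel and platelet lineages, rested on 27 and 34 cells. Endothelial genes were higher in these cells. PPBP, a platelet chemokine, rose by 5.98 (6.73 and 5.19) to 138 ± 57.2 CPM, and the antimicrobial peptide CAMP by 4.35 (5.44 and 3.14), FCER1G by 3.76 (4.91 and 1.97) and CCL5 by 3.66 (4.49 and 2.68). CCK and NPTX2 were lower by 3.09 (2.13 and 8.17) and 2.67 (2.52 and 2.77), with 2 and 4 UMIs left in FLI1 cells. Of 16 endothelial genes 7 rose and 0 fell (9 adjusted over the list alone), with a median of 1.61, or 1.79 with undetected genes at their bound. The erythroid and megakaryocyte list, with 1 of 10 members up, was not called. The roundabout receptor ROBO4 rose by 5.20 (4.96 and 4.94), CD34 by 4.16 (4.83 and 3.00), PLVAP, a protein of vessel wall openings, by 3.88 (3.90 and 3.82) and ESAM by 3.41 (3.87 and 2.88), from 9, 11, 38 and 10 UMIs. In the myeloid list 7 of 21 rose and 1 fell (8 adjusted over the list alone), with CYBB at 3.28 (3.77 and 2.68) and LYZ at 3.05 (4.28 and 1.25), and the interferon list (7 of 12 up, 10 adjusted over the list alone) and the stress list (4 of 13 up, 1 down, 9 adjusted over the list alone) were raised too. By camera the adjusted p was 6.0e-07 for endothelial genes, and 0.895 as adjusted p with an estimated correlation for all 4 lists. FLI1 was also carried forward by the study, so the lists are not independent evidence. CYBB and LYZ were also higher in CEBPA cells, and the share of FLI1 cells that carried CEBPA is not given here. Too few FLI1 cells were left for the comparison without CEBPA and SPI1 cells, so its myeloid rise was not checked there.

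The FLI1 fit called 753 genes, 381 up and 372 down, beyond the 193 of the largest random set of that size. DESeq2 called 213, of which 84.5% were up against 50.6%, and FCER1G, LYZ, CCK and NPTX2 no longer passed there. ROBO4, CD34 and ESAM lost their calls in thinned cells, ESAM with the TF call at 1 count, and CCK in thinned cells, without the library block and against unbarcoded cells.

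Shifts of the microglia or myeloid list were smaller with several other TFs. With KLF6, 8 of 15 microglia genes rose and 1 fell (9 adjusted over the list alone, median 0.32) and 12 of 21 myeloid genes rose (15 adjusted over the list alone, median 0.53). P2RY13 was at 2.78 (2.97 and 2.19), from 44 UMIs in KLF6 cells, and LYZ at 1.63 (2.08 and 1.14). The microglia gene that fell had the largest change of that list, C1QB at −2.88 (−1.80 and −2.88), with 2 UMIs in KLF6 cells. Besides P2RY13, the microglia genes that rose did so by at most 0.75. In KLF6 cells the mesenchymal (10 of 16 up, 1 down, 11 adjusted over the list alone), stress (4 of 13 up, 9 adjusted over the list alone) and interferon lists (9 of 12 up, 1 down, 11 adjusted over the list alone) were raised. The pluripotency (13 of 13 down, 13 adjusted over the list alone) and cell cycle lists (11 of 15 down, 12 adjusted over the list alone) were lowered, and for all 7 lists of KLF6 the adjusted p was 0.895 with an estimated correlation. In TAL1 cells 6 of 17 microglia genes rose and 2 fell (11 adjusted over the list alone, median 0.16), and 8 of 16 endothelial genes rose and 1 fell (13 adjusted over the list alone, median 0.38), both with an adjusted p of 0.895 with an estimated correlation. The vessel genes CDH5 and CD34 were at 1.98 (1.74 and 1.69) and 1.82 (1.54 and 1.84) and C1QA at 1.64 (2.08 and 0.87).

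The myeloid list in IRF1 cells had 7 of 22 members up and 2 down (11 adjusted over the list alone, median 0.43), with CTSS at 3.26 (3.35 and 3.13) and FCGR2A at 3.12 (3.21 and 2.96). Shifts of this list were smaller with HCLS1 (1 of 21 up, 4 adjusted over the list alone, median 0.31, 0.16 and 0.68 in the libraries), BATF3 (6 up, 1 down, 11 adjusted over the list alone, median 0.20) and FOS (3 up, 2 down, 6 adjusted over the list alone, median 0.10). For the lists of these TFs the adjusted p was 0.895 with an estimated correlation. With CEBPA and SPI1 cells left out, a comparison chosen after seeing the data, the microglia list of KLF6 (0.17) and the myeloid lists of IRF1 (0.02) and HCLS1 (0.19) were no longer called. The microglia list of TAL1 lost its call in thinned cells (0.13) and with the stricter TF call (0.18), and its median was −0.27 in cells with exactly 1 TF. The myeloid lists of IRF1, HCLS1 and FOS lost their calls with the stricter cell filter, those of IRF1 and FOS in thinned cells, and that of FOS without the library block, and CDH5, CD34 and C1QA of TAL1 cells lost theirs under 3 or more alternatives.

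SPI1 cells with and without CEBPA were compared to see what CEBPA added. Leukocyte and myeloid genes were higher in cells with both, and pluripotency genes were lower. LYZ stood at 467 ± 142 CPM in cells with both TFs (220 and 282 cells) and 10.7 ± 1.49 in SPI1 cells without CEBPA (355 and 457 cells), a log2 fold change of 5.39 (5.85 and 4.94). AIF1 went the other way, at 41.4 ± 18.7 against 118 ± 1.13 CPM, a log2 fold change of −1.56 (−1.11 and −2.04). Altogether 3021 genes rose and 2456 fell of 14221 tested by edgeR's quasi-likelihood test.

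Strong increases with CEBPA were seen in SERPINB2 (6.93, 5.50 and 6.80), the thioesterase OLAH (5.79, 5.13 and 5.52), the chemokine CCL20 (5.68, 5.22 and 6.78) and ANKRD22 (5.64, 5.24 and 5.48), and strong falls in APELA, a peptide of stem cells (−5.25, −5.64 and −4.14), and ARPP21 (−5.04, −3.57 and −6.24). In the microglia list 8 of 15 genes rose and 1 fell (10 adjusted over the list alone, 9 of them up, median 0.62, 1.18 and 0.42 in the libraries). GPR34 was at 3.43 (4.44 and 2.27), P2RY13 at 2.84 (2.98 and 1.89), C3 at 2.59 (2.94 and 2.25) and TREM2 at 2.34 (2.86 and 1.88). In the myeloid list 15 of 19 rose and 3 fell (18 adjusted over the list alone, 15 of them up, median 2.13), with S100A9 at 4.93 (5.51 and 4.38), S100A8 at 4.86 (5.45 and 4.31) and SRGN at 2.05 ± 0.43 against 0.09 ± 0.12 CPM, from 28 UMIs against 2. The members that fell were PTPRC at −3.05 (−1.62 and −4.54), CD53 at −2.87 (−2.13 and −3.45) and CD33 at −1.22 (−1.41 and −1.02), which with AIF1 were chosen after their values were seen. PTPRC rested on 7 UMIs in cells with both TFs against 110.

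Pluripotency genes fell in SPI1 cells that also had CEBPA (12 of 13, 12 adjusted over the list alone, median −1.89), including TDGF1 at −3.96 (−3.88 and −3.79), LIN28A at −3.58 (−3.36 and −3.79) and SOX2 at −2.55 (−2.62 and −2.46). The neural (5 of 6 down, 5 adjusted over the list alone), primitive streak (5 of 6 down, 1 up, 6 adjusted over the list alone), mesenchymal (9 of 13 down, 2 up, 11 adjusted over the list alone) and cell cycle lists (12 of 15 down, 13 adjusted over the list alone) were lowered. The inflammatory (8 of 10 up, 2 down, 10 adjusted over the list alone), interferon (11 of 12 up, 12 adjusted over the list alone) and stress lists (8 of 12 up, 1 down, 11 adjusted over the list alone) were raised. Both TFs were chosen by the study on these libraries, so these counts are not independent evidence. No list passed with an estimated correlation (adjusted p = 0.573 to 0.609 with an estimated correlation), which with 4 sums per fit does not decide the calls. With the TF call at 1 count the primitive streak list was not lowered (median 0.04), the microglia, mesenchymal and cell cycle lists, P2RY13, CD53 and PTPRC lost their calls, the stress list lost its call under 3 alternatives and the inflammatory list with the stricter cell filter, and ARPP21, PTPRC and CD33 did so under DESeq2, which called 1689 genes, 66.0% of them up against 55.2%.

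**Figure D4:**
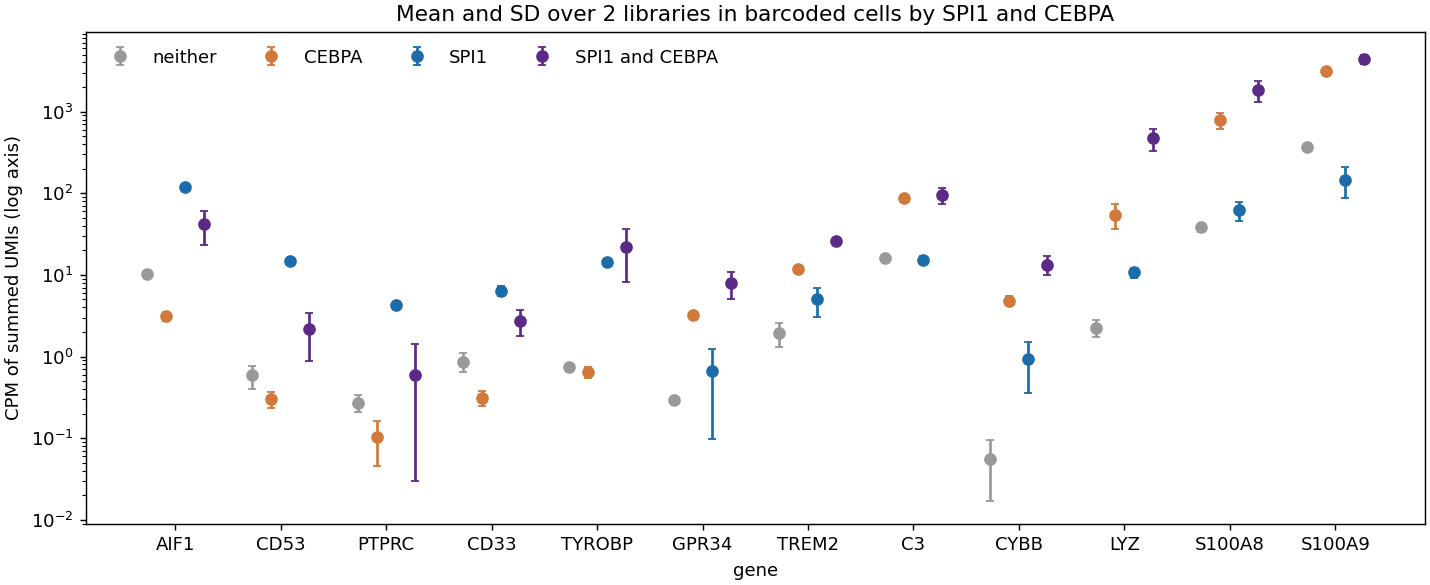
Expression (CPM, log axis) of microglia and myeloid genes in barcoded cells with neither SPI1 nor CEBPA, with 1 of them, and with both, as mean ± SD over 2 libraries, with lower bars shortened where the SD nears or exceeds the mean. LYZ is highest in cells with both TFs at 474 CPM, while AIF1 is highest with SPI1 alone at 119 CPM. The figure scales all 4 classes together, so its CPM differ slightly from those of the comparison of 2 classes.

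FLI1 with SPI1 was found in 8 cells, 4 per library, which is below the limit for a test. Their summed LAPTM5 was 161 CPM (exact counting interval 109 to 230) against 75.8 in other SPI1 cells, and AIF1 was 69.8 (37.2 to 119) against 90.9. TYROBP was 5.37 (0.136 to 29.9) against 16.5, and LYZ was 5.37 (0.136 to 29.9) against 169, each from 1 UMI in these cells. These intervals cover counting error and not the spread between cells, and CEBPA in these cells was not taken into account, so no difference is concluded.

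Clustering of all cells gave 9 groups. Clusters 0 and 8, with 1238 and 124 cells, had pluripotency genes such as POU5F1 among their leading genes and are called pluripotent-like. Of the unbarcoded cells, cluster 0 held 357 of 409 in library 1 and 263 of 319 in library 2, and cluster 8 held 22 and 31. Cells with a called TF made up the rest of both clusters, out of 693 and 545 cells in cluster 0 and 50 and 74 in cluster 8. Many cells with a called TF thus lay in pluripotent-like clusters. Cluster 0 had a median of 42856.5 UMIs, against 45206 and 43983 in unbarcoded and 28058 and 28165 in barcoded cells. Whether its barcoded cells were TF cells that stayed pluripotent or added stem cells with a TF called in error was not tested. Cluster 1, with 2115 cells (21.4% of each library), was led by COL1A2, COL1A1 and TAGLN and is called mesenchymal-like. Clusters 4 and 6 each had 9 leukocyte and myeloid genes at least 2-fold higher, with none among their 10 leading genes, and stayed unnamed like clusters 2, 3, 5 and 7. Cluster 4 had the most microglia genes, 4 of them, also with none among the leading genes, so no cluster was called microglia-like. Among the unnamed clusters, cluster 3, with 164 cells, had 8 interferon and MHC class I genes at least 2-fold higher. Of these, 3 were among its 10 leading genes. The number of clusters was 6 at a resolution of 0.3 and 22 at 1.0.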

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

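The test of whether the effect of CEBPA differs with SPI1 was chosen after the data had been seen, as were the tests on equal depth, on shallow cells and on cells without CEBPA.

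A different effect of CEBPA in cells with and without SPI1 was called for some genes. By an interaction term in edgeR's quasi-likelihood test over the 4 classes of cells in both libraries, 167 of 17536 genes passed, 83 with a more positive and 84 with a more negative effect in SPI1 cells, and 101 passed without the library block. On simulated data 14.3% of the calls of this test were false, above the nominal share. Random sets of cells were not run for this test. For the TFs where they were run, their median number of calls exceeded the false calls of the simulation. The false share among the 167 genes may therefore be higher, and single genes are uncertain, most of all near the threshold. Genes of the microglia and myeloid lists more positive in SPI1 cells were S100A9, FCGR2A and OLFML3. The difference was 1.80 log2 units for S100A9 (2.28 and 1.46 in the libraries), 1.89 for FCGR2A, an antibody receptor of phagocytes (2.29 and 1.37), and 0.74 for OLFML3 (1.07 and 0.45). For AIF1, whose level was lower with CEBPA, the difference was 0.18 and did not pass.

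More SPI1 RNA in cells that also carried CEBPA could give such differences, but SPI1 itself differed by only 0.20 ± 0.10 log2 units (SE, 0.41 and −0.01 in the libraries) between SPI1 cells with and without CEBPA. Genes near the detection floor are argued against as the whole cause, as 73.1% of the 167 genes had at least 100 UMIs in each class. Joint action of both factors on S100A9 may therefore be followed up as a hypothesis. Other TFs carried by the same cells remain open, and no biological explanation beyond the TF groups was tested.

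The rise of myeloid genes in SPI1 cells could come from CEBPA in the same cells. CEBPA was carried by 38.3% and 38.2% of SPI1 cells and by 44.1% and 43.5% of other barcoded cells, and with CEBPA cells left out the list median was 2.28 (2.16 and 2.17 in the libraries) in place of 1.79. Deeper SPI1 cells are argued against as well, because SPI1 cells had medians of 28773 and 27976 UMIs against 27978 and 28273.5 in other barcoded cells, and were thus not deeper in library 2. The list median was 1.57 (1.78 and 1.25) with cells thinned to equal depth. An effect of SPI1 on these genes remains as a hypothesis, and whether TFs other than CEBPA add to it was not tested.

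Cells without a called TF had high pluripotency genes, which the added stem cells would give. They could also be TF cells whose barcode was missed in shallow droplets. Their median UMI count was 1.61 and 1.56 times that of barcoded cells, so shallow droplets do not account for the group as a whole. A median cannot exclude a shallow minority. Under 16053 UMIs lay 43 of 409 and 34 of 319 unbarcoded cells, and 462 of 4520 and 449 of 4627 barcoded cells. Cells missing from the TF table did not set the result, since the list median was −2.53 and −2.74 in the libraries with them left out. That some stem cells of the sort rather than the added ones lie in this group stays open.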

How the results depend on the processing

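Each count was recomputed under the alternatives fixed in advance and 1 chosen after seeing the data, the comparison without CEBPA and SPI1 cells. Among named genes 1922 values kept direction and call, 52 kept direction and lost the call and 31 reversed, and among list medians the numbers were 269, 19 and 2. The kept values include 169 gene values and 29 list medians from an alternative that asked for 50 cells per group. It only dropped TFs with fewer cells and used the same sums for the rest, so these add no evidence. With 1 library alone, which allows no test, no printed gene and none of the called list medians examined reversed. Of these, 39 gene values and 20 list medians moved by more than the SD of the 2 libraries. The rule asked for 1 direction in both libraries and examples were selected after their values were seen, so this does not test direction. Called picks that are not printed could differ, such as IFIT1 in TAL1 cells (0.77 and −0.18). A single library usually lies within that SD of the fit, so staying within it says little. The cause of the changes that follow was not tested. By design, fewer cells enter with single-TF cells, stricter filters and thinning. With the TF call at 1 count, most cells unbarcoded in the main call join the barcoded cells. That call thus also changes the reference, and values that reverse both there and against unbarcoded cells are not independent checks.

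With DESeq2 the number of called genes was 8359 for barcoded cells, 6416 for CEBPA, 2858 for CEBPB, 3299 for ZFP36, 1969 for ZFP36L1, 1493 for JUN, 1527 for SPI1, 213 for FLI1 and 1689 for SPI1 with CEBPA. The share of calls that were up became 70.7% (56.7% with edgeR) for SPI1, 84.5% (50.6%) for FLI1, 66.0% (55.2%) for SPI1 with CEBPA and 32.9% (43.3%) for ZFP36L1. The stricter cell filter gave 1602 genes for SPI1, 2735 for ZFP36L1, 2326 for JUN, 1991 for SPI1 with CEBPA, and 88.8% of cells with a TF. Thinned cells gave 354 genes for FLI1 and 3546 for SPI1 with CEBPA. Without the low-count filter the median of all genes moved from 0.06 to 0.32 for barcoded cells and from −0.09 to −0.42 for FLI1, and at a Leiden resolution of 1.0 the clusters numbered 22.

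With the TF call at 10 counts and 10% SPI1 had 3089 genes and 90.2% of cells had a TF. The TF call at 1 count, without the rule on the share, gave 8433 genes for barcoded cells, 8470 for SPI1, 9613 for ZFP36L1, 8109 for JUN and 4874 for FLI1, 35 TFs with a raised microglia or myeloid list, and 98.0% of cells with a TF. Under it the log2 fold changes that reversed were FYB 0.20, LYZ 0.98 and COL1A2 0.13 with CEBPB, TAC1 0.61, SRGN 0.80 and FCER1G 0.50 with ZFP36, LEFTY2 −0.064, FCER1G 1.18 and S100A8 0.22 with ZFP36L1, CCK 0.33 with SPI1, TDGF1 −2.33 and LIN28A −1.17 with STAT3, LIN28A −1.35 and SOX2 −0.85 with ATF4, and the primitive streak list median 0.044 in SPI1 cells with CEBPA.

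In cells with a single TF, 2 TFs could be tested, of which 2 had changed genes, the own gene rose for 2 and a raised microglia or myeloid list was found for 0. There CEBPB had 353 genes, and the microglia list median of TAL1 was −0.27. Without CEBPA and SPI1 cells LYZ was 0.29 with CEBPB. With unbarcoded cells as reference the counts were 12150 for CEBPB, 11718 for ZFP36, 11741 for ZFP36L1, 11258 for JUN, 10823 for SPI1 and 4862 for FLI1, and 32 TFs had a raised microglia or myeloid list. Reversed values against that reference were FYB 2.43 and LYZ 2.81 with CEBPB, TAC1 1.02, SERPINB2 2.83, LYZ 2.47, FCER1G 1.69 and S100A8 3.22 with ZFP36, CCK 0.23, FCER1G 1.94 and S100A8 3.45 with ZFP36L1, CCK 0.58 with SPI1, TDGF1 −2.22 and LIN28A −1.39 with STAT3, LIN28A −1.37 and SOX2 −0.65 with ATF4, and ITGB2 1.47 with RUNX1.

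Without the replicate block the count for FLI1 was 489, for JUN 3658, for SPI1 3391 and for barcoded cells 12460, 31 TFs had changed genes and 9 a raised list. For FLI1 simulated data gave back 23.2% of genes changed 2-fold, the lowest share among the comparisons simulated, and TFs with similarly few cells were not simulated.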

Other observations

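The grouping of TFs by protein family was written before the correlations but after the list results of each TF had been seen. The genes HLA-DRA, HLA-DRB1 and CD74 in CIITA cells were chosen after their values were seen, and the other genes are examples taken from the fixed lists.

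Some TFs moved gene groups that have not been described so far. CIITA, the master regulator of MHC class II genes, was carried by 120 and 93 cells, in which HLA-DRA rose by 3.32 log2 units (3.40 and 3.23 in the libraries) to 1914 ± 57.7 CPM against 193 ± 21.2 in other barcoded cells (n = 2 libraries). HLA-DRB1 and the invariant chain CD74 rose by 3.10 (3.19 and 3.01) and 2.82 (2.94 and 2.71), and the class I genes HLA-B and HLA-C by 2.04 (2.02 and 2.06) and 1.69 (1.68 and 1.70). Of the interferon and MHC class I list 5 of 12 members rose and 0 fell in CIITA cells (6 adjusted over the list alone), with an adjusted p of 0.895 with an estimated correlation by camera. In IRF1 cells (83 and 72) all 12 members of that list rose (12 adjusted over the list alone, median 1.80, adjusted p = 6.0e-11 by camera and 0.895 as adjusted p with an estimated correlation). IFIT3 was at 2.52 (2.48 and 2.56), OAS1 at 2.39 (2.98 and 1.52) and MX1 at 2.29 (2.34 and 2.23).

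RUNX1, a blood cell factor, went with a lowered myeloid list in relation to other barcoded cells, with 11 of 21 genes down and 4 up (16 adjusted over the list alone, 5 of them up, median −0.91, adjusted p = 0.895 with an estimated correlation by camera). The NADPH oxidase gene CYBB was at −2.50 (−1.80 and −3.52) and ITGB2 at −2.41 (−2.46 and −2.32), while SRGN was at 3.04 (3.38 and 2.61). Genes of other cell types rose in the same cells, with LUM at 3.12 (3.13 and 3.09), COL1A2 at 1.53 (1.61 and 1.45), STMN2 at 2.32 (2.23 and 2.32) and NEFL at 1.80 (1.55 and 2.01), although the mesenchymal (6 of 16 up, 3 down, 9 adjusted over the list alone, median 0.13) and neural lists (5 of 12 up, 1 down, 7 adjusted over the list alone, median 0.29) were not called. RUNX1 cells carried CEBPA in 28.8% and 34.3% against 44.3% and 43.3% of other barcoded cells. ITGB2 was higher by 1.47 against unbarcoded cells and lost its call with the TF call at 1 count, and SRGN lost its call without CEBPA and SPI1 cells. NEFL and STMN2 lost theirs against unbarcoded cells and with the TF call at 1 count, and STMN2 also with the stricter cell filter.

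The pluripotency list was higher than in other barcoded cells with STAT3 (9 of 13 up, 13 adjusted over the list alone, median 0.82, 0.27 and 1.29 in the libraries) and ATF4 (11 of 13 up, 11 adjusted over the list alone, median 0.67), each with an adjusted p of 0.895 with an estimated correlation by camera. TDGF1 and LIN28A were at 1.51 (0.99 and 1.98) and 1.19 (0.94 and 1.44) with STAT3, and LIN28A and SOX2 at 1.20 (1.19 and 1.23) and 1.00 (1.09 and 0.88) with ATF4. Against unbarcoded cells these genes were lower, TDGF1 and LIN28A by 2.22 and 1.39 with STAT3 and LIN28A and SOX2 by 1.37 and 0.65 with ATF4. They were also lower with the TF call at 1 count, TDGF1 and LIN28A by 2.33 and 1.17 with STAT3 and LIN28A and SOX2 by 1.35 and 0.85 with ATF4. STAT3 and ATF4 cells carried CEBPA in 32.0% and 25.0%, and 28.8% and 27.1%, against 43.4% to 43.5% in library 1 and 42.8% in library 2 of other barcoded cells. The share of STAT3 and ATF4 cells in the pluripotent-like clusters was not measured, so the higher list may reflect it.

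A hypothesis was that TFs of a protein family give alike profiles. For each pair of 32 TFs, cells with both were left out and log2 profiles over 4738 genes were correlated across the libraries, 1 TF from each. Pearson's r averaged 0.369 over 39 pairs within families and 0.0961 over 457 pairs between them, a difference of 0.27 (one-sided permutation test of family labels, 100000 permutations, p = 4.0e-05). Genes are not independent replicates, and all profiles share reference cells. The highest values were 0.848 for ZFP36L1 and ZFP36L2, 0.786 for JUN and JUNB, 0.716 for ZFP36 and ZFP36L2 and 0.683 for CEBPA and CEBPB, against a median of 0.706 for the same TF between libraries. The same-TF values ran from 0.242 to 0.989. SPI1 and FLI1, both ETS factors, had an r of 0.103, where FLI1, with 27 and 34 cells, reached 0.510 with itself between libraries.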
